A study of Mus musculus with 8 samples.

How the data were processed

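Gene expression was measured by sequencing of polyadenylated RNA from 8 mouse hearts, described as whole and taken 7 days after surgical narrowing of the aortic arch. Per the labels, 4 hearts carried the Cre recombinase under the alpha myosin heavy chain promoter and served as controls (ACRE), and 4 were cardiomyocyte-specific Smad7 knockouts made with the same Cre (CMS7KO). The labels describe the 4 samples of each condition as independent. They give replicates 1 and 2 of each group as male and replicates 3 and 4 as female. The labels do not state littermates, surgery days or library batches, so no batch could be fitted.

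The authors deposited 1 table of whole-number read counts per gene with 8 columns, 1 per heart, which were not normalized. The submitters' processing notes name CASAVA, TopHat2 2.0, Cufflinks 2.1.1 and HTSeq 0.6.1 and the builds mm10 and GRCm38.p6, without saying which step used which. The strand setting and annotation release are not given in the sources used here. Of 52073 identifiers shared with GENCODE mouse release 21 on GRCm38, 1485 (2.85%) had the same start as in the table. Smad7, for example, starts at 75367529 in that release and at 75500600 in the table. The build of the table's coordinates is therefore not named here, and positions are printed as the table gives them.

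Libraries held 12920435 to 17199600 reads counted in genes. The table lists 56748 genes, of which 32514 had at least 1 read. At these depths the 95% exact binomial interval of a library's mitochondrial share, or of the share of its 10 most abundant genes, extended at most 0.0238 percentage points to either side. A count of 0 was taken to allow up to 3 reads in that library. These intervals and limits cover counting error only, because reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise over genes with at least 20 reads per pair (smallest chi-square per degree of freedom 17.5), so each counted as 1 replicate.

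Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr on the 4 combinations of genotype and sex label, which left 16780 genes. Libraries were scaled by the trimmed mean of M values (TMM), with factors of 0.803 to 1.13. Expression levels are TMM-scaled read counts relative to library size (CPM), given as mean ± SD over 4 libraries. The genotype effect, CMS7KO minus ACRE, was tested by edgeR's robust quasi-likelihood F test with the sex label as covariate and 5 residual degrees of freedom. This label did not match sex-linked transcripts in ACRE 3 and CMS7KO 3, and no fit used a sex read from transcripts. The common biological coefficient of variation was 30.3%. P values were adjusted by the Benjamini-Hochberg method over the genes tested, at a threshold of 0.05. The SE of a log2 fold change was taken as its size over the square root of F. The same fit gave the effect of the sex label, and a fit of the 4 combinations gave the interaction and the genotype effect within each sex label, with 2 libraries per combination. For Smad7, a two-sided exact permutation test of log2 CPM over the 70 assignments of 8 libraries was added. Its smallest possible p is 0.0286.

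Gene lists covered 34 pathways or complexes and 19 cell types. Of these, 33 and 17 had at least 5 tested members. The replication-dependent histone list matched 0 genes under the symbols used, and the neutrophil list and the lung epithelial and thymic list had 3 tested members each, so these were not tested with all 8 libraries. Lists were compared with all other genes by limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, then with a correlation estimated for each list. They were also tested by limma's fry, whose directional test asks whether members move on balance the same way and whose mixed test asks whether they change in either direction. Neither fry test compares a list with other genes. Adjustment was over all lists of a kind. A list score is the mean over members of log2 CPM minus the gene's mean over the 8 libraries. The score's exact permutation p was added after the data were examined. Cell type lists share members with pathway lists: 9 of 12 for activated fibroblast, 11 of 12 for cardiomyocyte, 6 of 12 for atrial cardiomyocyte, 5 of 12 for fibroblast, 2 of 14 for macrophage and monocyte, and at most 2 in every other list.

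The groups, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named Smad7 and, by genotype, up to 12 genes per direction with the largest log2 fold change among those past the threshold. Such a gene had all 4 libraries of one genotype above the 4 of the other and a mean of at least 5 CPM in the higher group. Predicted or clone-named genes, pseudogenes and sex-linked genes were left out. Because fewer than 10 genes passed, the 10 smallest p per direction were named as values only. The rule also named up to 4 members with the smallest p in each called list, in the pathway lists of most interest and in each cell type list. For the sex label and the interaction it named the 5 smallest p per direction, outside predicted genes and, for sex, outside genes on X and Y. Genes named outside the rule are identified as chosen after their values were seen. Values of some genes that the rule names are not reported here.

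On simulated counts with the fitted spread and 16780 genes, the edgeR test recovered 46% of 50 genes raised by 1 on the log2 scale and 44% of 50 lowered by as much. It recovered 96% and 88% of those raised and lowered by 2, and 4 of its 141 calls were false. The changed genes were drawn from those with a mean above 50 reads. Genes were simulated independently, with no sex effect and no other structure among libraries. These rates therefore do not extend to genes with fewer reads or to libraries that stand apart.

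Alternatives were DESeq2 size factors in edgeR, library totals without a composition factor, DESeq2's own Wald test, limma voom with quality weights, no low-count filter, and a filter of at least 1 CPM in 4 libraries. Others were leaving out the 13 mitochondrially encoded genes and the 10 most abundant genes, no sex covariate, the replicate number as a block, leaving out each library in turn, an estimated correlation for lists, and log2 CPM means with a prior count of 2. A further 4 were chosen after seeing the data: leaving out ACRE 2 and 4, leaving out ACRE 3 and CMS7KO 3, an offset removing smooth trends on GC content and gene length, and edgeR's bias-adjusted quasi-likelihood. GC content came from GENCODE release 21 transcripts and was known for 98.1% of tested genes and 100% of pathway list members. Figures were drawn with matplotlib.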

Results

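RNA sequencing profiled hearts of 8 mice 7 days after constriction of the transverse aorta, an operation that loads the left ventricle with pressure. The 4 control hearts carried a cardiomyocyte Cre transgene (ACRE), and the other 4 were labelled as cardiomyocyte-specific knockouts of Smad7 (CMS7KO), an inhibitor of signalling through the TGF-beta receptor and Smad2/3. Libraries labelled ACRE 1 to 4 held 15875065, 17199600, 15046871 and 12920435 counted reads, and CMS7KO 1 to 4 held 13115418, 17147942, 14819239 and 13529234. Mitochondrially encoded genes took 16.4% (95% exact binomial interval 16.40 to 16.44%) of reads in ACRE 1 and 23.5% (23.49 to 23.53%) in CMS7KO 4, the lowest and highest shares. Correlations of log2 CPM between libraries were 0.941 to 0.977 within groups and 0.923 to 0.963 between groups. The first principal component held 37.5% of the variance. On it ACRE 2 and ACRE 4 scored 63.6 and 76.4, while the other 6 libraries scored -48.0 to -11.3. The second component held 17.4%, with scores of -48.2 and -47.8 for ACRE 1 and 3, 5.16 and 3.62 for ACRE 2 and 4, and 17.7 to 26.9 for the libraries labelled CMS7KO.

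**Figure D1:**
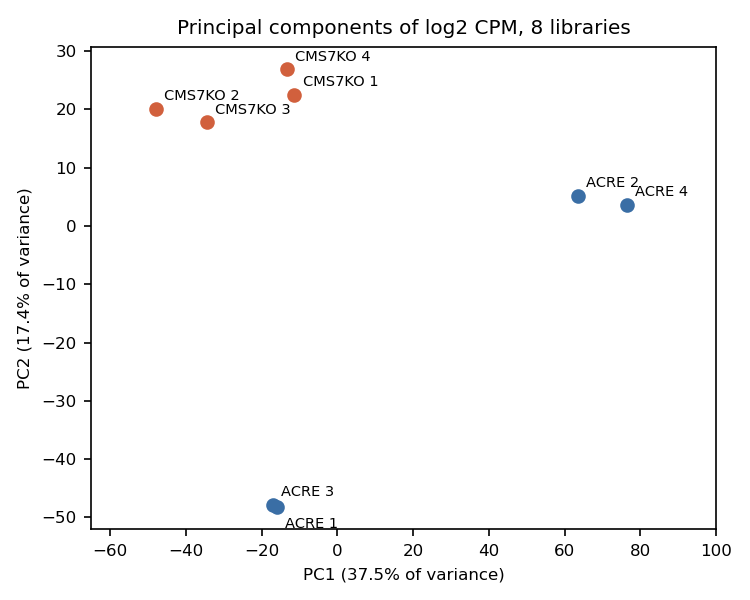
Scores of the 8 libraries on the first (x axis, 37.5% of variance) and second (y axis, 17.4%) principal components of log2 CPM, blue for ACRE and orange for CMS7KO. ACRE 2 and 4 lie at 63.6 and 76.4 on the x axis, apart from the other 6 libraries.

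Transcripts of Smad7, the targeted gene, were not lower in the libraries labelled CMS7KO. Smad7 (ENSMUSG00000025880, chromosome 18, 75500600 to 75529006) stood at 34.6, 34.5, 32.7 and 23.9 CPM in ACRE 1 to 4 and at 30.9, 41.9, 38.9 and 43.1 CPM in CMS7KO 1 to 4, from 248 to 807 reads per library. The means were 31.4 ± 5.07 CPM in ACRE and 38.7 ± 5.47 CPM in CMS7KO (SD, n = 4 each), a log2 fold change of 0.30 (SE 0.18, edgeR adjusted p = 0.415). The ratio of 1.23 had a 95% confidence interval of 0.939 to 1.62, and a two-sided exact permutation test gave p = 0.114. These are counts over the whole gene in heart tissue and not in cardiomyocytes alone. Other cell types also express Smad7 and a partly deleted gene can still be transcribed, and exon-level reads were not analysed here. The level of Smad7 therefore does not check the labels, and every direction by genotype below rests on the labels alone.

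The genotype comparison asked which genes differ in the pressure-loaded heart when cardiomyocytes lack Smad7, as the libraries are labelled. In the libraries labelled CMS7KO 3 genes were higher and 3 lower than in ACRE, among 16780 tested. Fbn2, which encodes the microfibril protein fibrillin-2, was 8.20-fold higher at 12.4 ± 5.06 against 1.55 ± 0.89 CPM (SD, n = 4 each; log2 fold change 3.03, SE 0.30, adjusted p = 0.0146). Grhl1, a transcription factor of epithelia, was 4.52-fold higher at 11.8 ± 2.03 against 2.63 ± 0.64 CPM (2.18, SE 0.23, adjusted p = 0.0184). Nrtn, which encodes the growth factor neurturin, was 3.45-fold higher at 67.6 ± 9.04 against 20.5 ± 7.26 CPM (1.79, SE 0.21, adjusted p = 0.0317). Ogdhl, a relative of the mitochondrial 2-oxoglutarate dehydrogenase, was 4.17-fold lower at 36.5 ± 2.76 against 155 ± 46.8 CPM (-2.06, SE 0.21, adjusted p = 0.0146). The other 2 lower genes were chosen after their values were seen: the long noncoding RNA ENSMUSG00000120208, at 0.677 ± 0.363 against 9.53 ± 4.54 CPM (-3.85, SE 0.31, adjusted p = 0.00571), and the pseudogene Gm31663, at 0.158 ± 0.106 against 4.73 ± 2.40 CPM (-4.90, SE 0.59, adjusted p = 0.0329). For all 6 genes the 4 libraries of 1 genotype lay above the 4 of the other.

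By the coordinates of the table, Fbn2 (ENSMUSG00000024598) lies on chromosome 18 from 58141695 to 58343559, Grhl1 (ENSMUSG00000020656) on chromosome 12 from 24622282 to 24667390 and Nrtn (ENSMUSG00000039481) on chromosome 17 from 57058325 to 57064530. Ogdhl (ENSMUSG00000021913) lies on chromosome 14 from 32043976 to 32070108, ENSMUSG00000120208 on chromosome 13 from 102486158 to 102494740, and Gm31663 (ENSMUSG00000108994) on chromosome 7 from 92629084 to 92655721. An unadjusted p under 0.05 was found for 2571 genes, 1195 higher and 1376 lower, where a uniform p gives 839. Of the other 34 splits of the 8 libraries into 4 and 4, 3 had more such genes, at 3944, 3218 and 2591. The 4 libraries labelled CMS7KO all lay above ACRE for 908 genes and all below for 701, together 9.59% of genes. An average split gives 2.86%. The share in other splits was not counted and genes can move together, so an excess over chance was not tested. The calls depended on the test and on single libraries: DESeq2 called 214 genes higher and 189 lower, the 6 included, and without ACRE 2 and 4, left out after seeing the data, edgeR called 86 and 89, again with the 6. Leaving out CMS7KO 1, 2 or 3 left 0 higher and 0 lower genes (edgeR, 2173, 1531 and 1487 unadjusted, among 17961, 17732 and 17886 genes that the filter then kept). Without ACRE 2 there were 10 and 7, without ACRE 3 there were 1 and 3, without ACRE 4 there were 7 and 4, and without CMS7KO 4 there were 2 and 5. Nrtn and Gm31663 lost their calls with an offset for GC content and gene length, Grhl1 with limma voom, Fbn2 without the sex covariate, Gm31663 without ACRE 1, Nrtn and Grhl1 without ACRE 3, Nrtn and Gm31663 without ACRE 4, Ogdhl, Nrtn and Gm31663 without CMS7KO 4, and all but ENSMUSG00000120208 without ACRE 3 and CMS7KO 3.

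**Figure D2:**
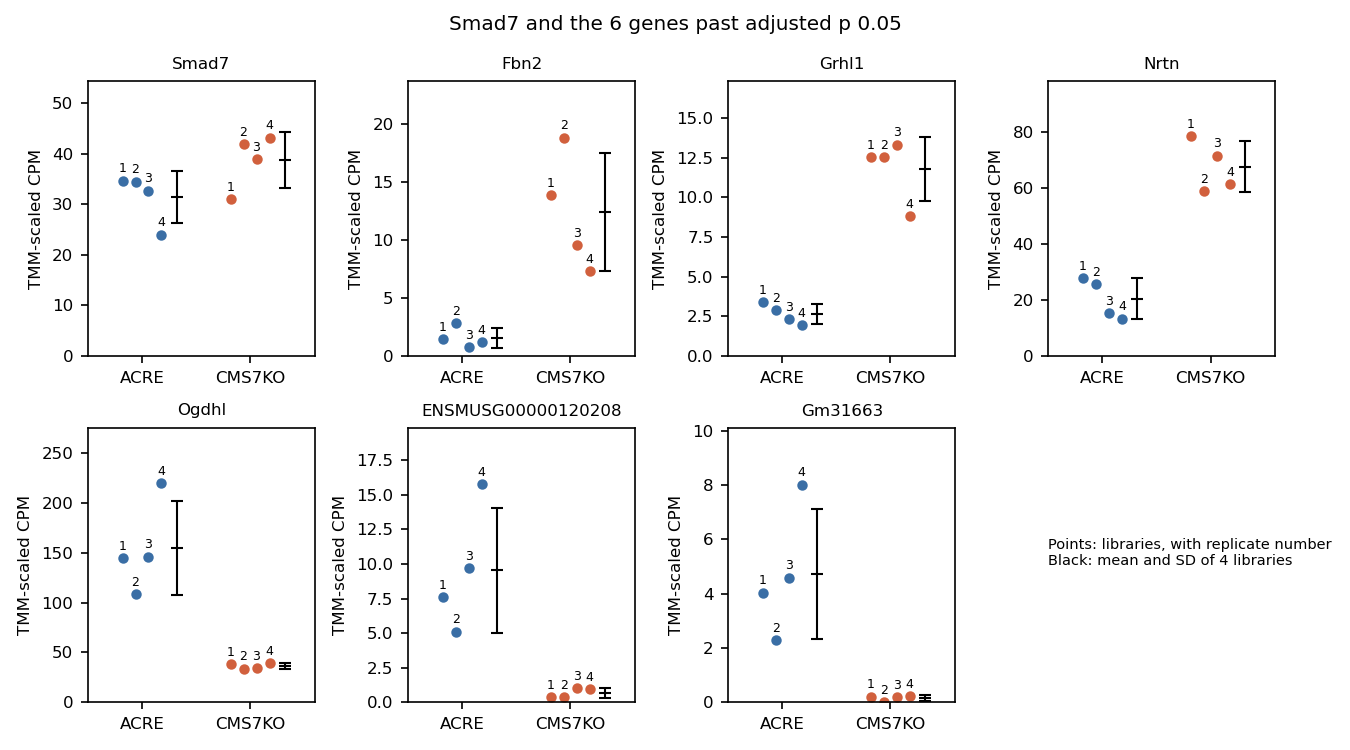
TMM-scaled CPM (y axis) of Smad7 and the 6 genes past adjusted p 0.05 in each library, by label (x axis), with the replicate number at each point and the mean ± SD of 4 libraries in black. Smad7 stood at 23.9 to 34.6 CPM in ACRE and 30.9 to 43.1 CPM in CMS7KO, and for the other 6 genes the groups did not overlap.

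Besides the called genes, the smallest p among genes higher in the libraries labelled CMS7KO belonged to genes that did not pass the threshold, with edgeR adjusted p of 0.106 to 0.150. All 7 named here passed an adjusted p of 0.05 with DESeq2. That is no independent support, since they were picked by the smallest edgeR p on the same counts. DESeq2 passed 22 of 23 genes named by genotype, and it called 1710 genes for a split that mixes the genotypes. Krt18, a keratin of simple epithelia, was at 7.51 ± 0.83 against 0.757 ± 0.727 CPM in ACRE (SD, n = 4 each), and Igfbp6, an insulin-like growth factor binding protein, at 39.7 ± 4.53 against 18.2 ± 3.50. Col8a2, a collagen chain, was at 10.5 ± 5.89 against 1.97 ± 0.695 CPM, and Carns1, carnosine synthase, at 107 ± 15.8 against 50.04 ± 6.42. The receptors Csf3r and Fzd2, for granulocyte colony-stimulating factor and Wnt proteins, were at 9.09 ± 1.09 against 3.68 ± 0.397 and 16.6 ± 4.33 against 6.69 ± 1.73 CPM. Prrx2, a mesenchymal homeobox factor, was at 2.31 ± 0.671 against 0.463 ± 0.262 CPM.

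Among genes lower in the libraries labelled CMS7KO, the next smallest p, with adjusted p of 0.0784 to 0.150 (edgeR), included several genes of the immediate-early response. All 9 named next passed an adjusted p of 0.05 with DESeq2, again on the same counts by which they were picked. The transcription factor genes Fos and Fosb were at 5.56 ± 2.01 against 28.4 ± 19.8 and 0.916 ± 0.250 against 5.91 ± 2.51 CPM (SD, n = 4 each). Dusp1, a phosphatase of mitogen-activated protein kinases, was at 79.9 ± 25.9 against 182 ± 59.0 CPM and Zfp36, an RNA-decay factor, at 30.5 ± 8.97 against 68.0 ± 25.7. The kinases Tnik and Wnk2 were at 12.98 ± 1.10 against 30.1 ± 4.97 and 24.5 ± 4.42 against 66.8 ± 26.8 CPM. Kcnv2, a potassium channel subunit, was at 1.47 ± 0.295 against 8.77 ± 4.34 CPM, Hacd1, an enzyme of fatty acid elongation, at 18.9 ± 1.70 against 33.2 ± 3.00, and Rasd1, a small GTPase, at 1.64 ± 0.885 against 6.15 ± 3.06. Dusp1 overlaps Ergic1 on the other strand, and Carns1 overlaps Gm17552. Whether reads were assigned by strand is not given in the sources used here.

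Matrix lists and the list of TGF-beta and Smad2/3 target genes ranked higher than other genes in the libraries labelled CMS7KO under a preset correlation of 0.01 and not with an estimated one, with no member past the threshold over all genes. The basement membrane and integrin lists were not called. Of 22 TGF-beta/Smad2/3 target genes 17 were higher and 5 lower (median log2 fold change 0.34, camera adjusted p = 0.000473, 0.637 with an estimated correlation), and 5 were higher adjusted over the list alone. Among them Pmepa1, a feedback inhibitor of this signalling, stood at 95.8 ± 32.7 against 46.3 ± 4.87 CPM (SD, n = 4 each). The latent-TGF-beta-binding protein gene Ltbp2 stood at 128 ± 73.0 against 41.4 ± 12.4 CPM, Tgfb1 at 64.1 ± 4.05 against 39.4 ± 9.62, and the transcription factor Snai1 at 8.27 ± 1.75 against 4.37 ± 0.849. Of 36 matricellular and structural matrix glycoproteins 31 were higher and 5 lower (median 0.61, camera adjusted p = 2.72e-08, 0.637 with an estimated correlation). Adjusted over the list alone 12 were higher and 1 lower, among them Cilp at 266 ± 83.9 against 106 ± 32.7 CPM and Thbs4 at 159 ± 134 against 35.8 ± 16.2, while Ccn1 stood at 51.4 ± 2.92 against 112 ± 53.6. All 16 fibrillar and fibril-associated collagens were higher (median 0.59, camera adjusted p = 1.53e-06, 0.637 with an estimated correlation; 1 adjusted over the list alone, Col8a2). They included Col1a1 at 719 ± 303 against 386 ± 72.7 CPM, Col16a1 at 55.3 ± 17.2 against 30.3 ± 7.57, and Col6a1 at 339 ± 86.4 against 225 ± 25.9. Of 40 matrix proteases, inhibitors and crosslinkers 27 were higher and 13 lower (median 0.28, camera adjusted p = 0.0257, 0.637 with an estimated correlation). Adjusted over the list alone, Mmp23 (40.1 ± 14.4 against 17.0 ± 3.80 CPM) and the crosslinking enzyme Loxl1 (173 ± 52.3 against 89.7 ± 11.2) were higher and Adamts1 (77.6 ± 13.2 against 129 ± 15.4) lower, while Pcolce, an enhancer of collagen processing, stood at 244 ± 20.2 against 150 ± 32.6.

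The scores of the target gene, glycoprotein and collagen lists were higher in all 4 libraries labelled CMS7KO than in any ACRE library. The exact permutation p of each was 0.0286, the smallest 4 against 4 can give, and 0.189 after adjustment over the pathway lists. This separation was not particular to them. BMP/Smad1/5 targets, a list that camera did not call, showed it with the same p. In all, 5 pathway and 5 cell type lists had every CMS7KO score above every ACRE score. The target gene scores were -0.26 to -0.14 in ACRE and 0.06 to 0.49 in CMS7KO. Without ACRE 2 and 4, left out after seeing the data, the medians of the target gene, glycoprotein and collagen lists were 0.42, 0.65 and 0.60 (camera adjusted p = 6.06e-05, 6.28e-09 and 1.57e-06), and that of the protease list was 0.27 (0.277). Without CMS7KO 2 the collagen median was 0.37 and the protease call ended (0.13, camera adjusted p = 0.166), as it did with limma voom (0.16, 0.175).

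Fibroblast and macrophage marker lists ranked higher than other genes under the preset correlation only, and 9 of the 12 activated fibroblast markers also stand in pathway lists. The macrophage scores did not follow the collagen scores by library: CMS7KO 4 had the highest macrophage score of its label (0.54) and the lowest collagen score (-0.17). All 12 activated fibroblast markers were higher in the libraries labelled CMS7KO (median log2 fold change 1.11, camera adjusted p = 1.17e-06, 0.305 with an estimated correlation), 6 of them adjusted over the list alone and 0 over all genes. Cilp, Thbs4 and Ltbp2 also stand in the matrix lists, and Meox1, a transcription factor gene, was at 102 ± 30.3 against 43.5 ± 13.99 CPM (SD, n = 4 each). All 12 fibroblast markers were higher (median 0.65, 0.39 without CMS7KO 2; camera adjusted p = 2.91e-05, 0.305 with an estimated correlation), 5 adjusted over the list alone. Tcf21 was at 18.4 ± 7.20 against 9.14 ± 1.08 CPM, Mfap5 at 223 ± 117 against 92.3 ± 27.0 and Dcn at 888 ± 188 against 549 ± 59.6. Of 14 macrophage and monocyte markers 12 were higher and 2 lower (median 0.71, camera adjusted p = 2.66e-05, 0.305 with an estimated correlation), 7 adjusted over the list alone. The receptor genes Trem2 and Cx3cr1 were at 18.5 ± 2.33 against 9.28 ± 1.26 and 21.2 ± 4.61 against 10.6 ± 3.96 CPM. The complement genes C1qa, C1qb and C1qc were at 154 ± 13.7 against 87.6 ± 26.9, 143 ± 11.7 against 81.8 ± 19.2 and 120 ± 13.9 against 60.5 ± 16.1 CPM, and C3ar1 was at 23.4 ± 2.99 against 15.6 ± 3.86. These 3 C1q genes were higher adjusted over the complement list alone, of which 14 of 16 members were higher and 2 lower (median 0.50, camera adjusted p = 0.000216, 0.637 with an estimated correlation). Scores of these 4 lists were higher in all 4 libraries labelled CMS7KO than in any ACRE library. The exact permutation p was 0.0286 each, which after adjustment was 0.0971 for the cell type lists and 0.189 for complement. The erythroid and platelet scores and the chondrocyte and bone scores were separated in the same way, with the same p (0.0971 adjusted).

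**Figure D3:**
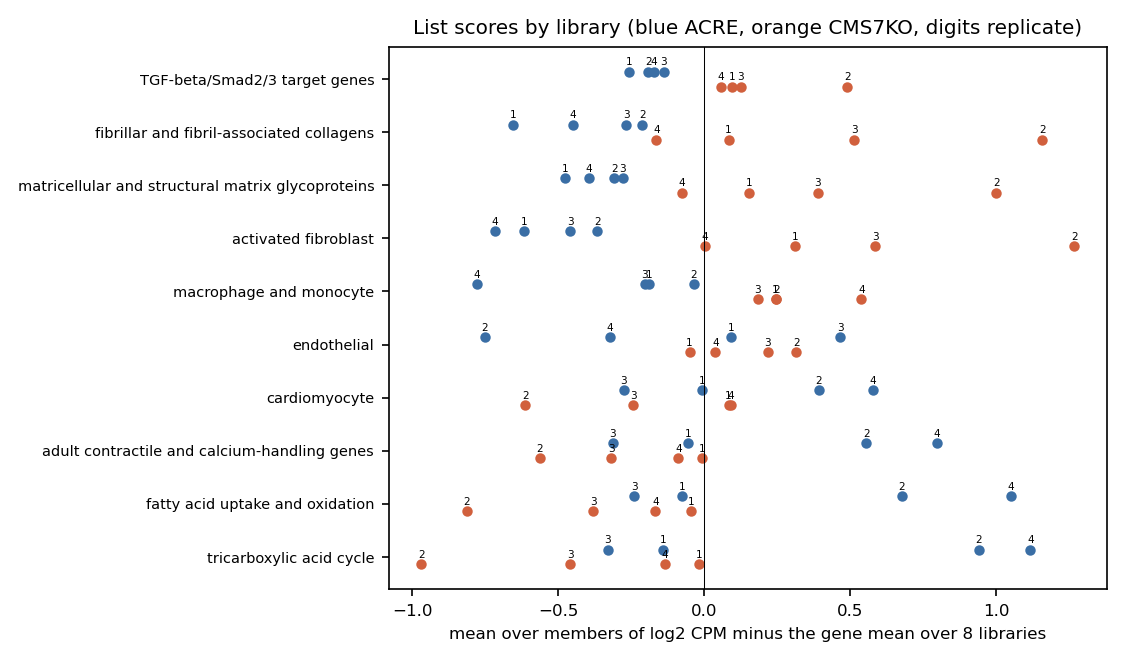
Score of 10 lists (y axis) in each library, as the mean over members of log2 CPM minus the gene's mean over 8 libraries (x axis), blue for ACRE, orange for CMS7KO and a digit for the replicate. The TGF-beta/Smad2/3 target scores lay at -0.26 to -0.14 in ACRE and 0.06 to 0.49 in CMS7KO, while the fatty acid scores of ACRE 2 and 4 lay at 0.68 and 1.05, above the other 6 libraries.

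Lists of oxidative metabolism, contraction and conduction ranked lower than other genes in the libraries labelled CMS7KO under the preset correlation only, with no member past the threshold over all genes. Of 32 genes of fatty acid uptake and oxidation 30 were lower and 2 higher (median log2 fold change -0.85, camera adjusted p = 3.73e-08, 0.637 with an estimated correlation). They included Acsl1, which activates fatty acids, at 200 ± 63.1 against 635 ± 430 CPM (SD, n = 4 each), Pdk4 at 58.7 ± 15.7 against 154 ± 93.9, Ucp3 at 11.8 ± 5.41 against 26.4 ± 3.59 and Mlycd at 39.2 ± 6.50 against 64.9 ± 19.2. All 18 genes of the tricarboxylic acid cycle were lower (median -0.96, camera adjusted p = 4.18e-07, 0.637 with an estimated correlation). Pdhb was at 306 ± 81.9 against 536 ± 110 CPM, Dld at 117 ± 33.4 against 308 ± 199, Ogdh at 736 ± 203 against 1921 ± 1302 and Pcx at 16.8 ± 4.53 against 32.8 ± 16.1. All 15 genes of branched-chain amino acid and ketone catabolism were lower (median -0.93, camera adjusted p = 3.60e-07, 0.637 with an estimated correlation). Adjusted over the list alone 5 were lower, among them Dbt at 16.6 ± 4.01 against 49.3 ± 29.8 CPM, Mccc1 at 38.4 ± 11.98 against 67.3 ± 14.6, Bdh1 at 47.7 ± 29.3 against 161 ± 141 and Aldh6a1 at 75.4 ± 11.5 against 180 ± 118. Of 43 nuclear-encoded subunits of oxidative phosphorylation 38 were lower and 5 higher (median -0.24, camera adjusted p = 0.000473, 0.637 with an estimated correlation). Ndufs1 was at 227 ± 63.3 against 496 ± 295 CPM, Uqcrc2 at 300 ± 95.3 against 642 ± 363, and Sdha at 455 ± 139 against 1014 ± 651. Of 26 adult contractile and calcium-handling genes 25 were lower and 1 higher (median -0.56, camera adjusted p = 0.000216, 0.637 with an estimated correlation). The calcium pump Atp2a2 was at 2604 ± 798 against 8031 ± 6019 CPM, Hrc at 252 ± 91.9 against 598 ± 288, Trdn at 125 ± 20.2 against 261 ± 117 and Asph at 95.1 ± 9.49 against 185 ± 65.7. Of 24 ion channel and conduction genes 19 were lower and 5 higher (median -0.52, camera adjusted p = 0.0337, 0.637 with an estimated correlation), and adjusted over the list alone 4 were lower and 2 higher. The potassium channel gene Kcnj2 was at 17.1 ± 3.15 against 34.8 ± 14.9 CPM, while the T-type calcium channel Cacna1g was at 94.8 ± 22.7 against 35.5 ± 17.9 and Kcne1 at 43.9 ± 10.8 against 14.1 ± 10.7.

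These differences moved with the libraries that stand apart. The fatty acid scores were 0.68 in ACRE 2 and 1.05 in ACRE 4, against -0.08 in ACRE 1, -0.24 in ACRE 3 and -0.81 to -0.05 in the libraries labelled CMS7KO. The tricarboxylic acid cycle scores were 0.94 and 1.12 in ACRE 2 and 4 against -0.14, -0.33 and -0.97 to -0.02, and the contractile scores 0.55 and 0.80 against -0.06, -0.31 and -0.56 to -0.01. Without ACRE 2 and 4, left out after seeing the data, the medians were -0.19 for fatty acid genes (camera adjusted p = 0.0213), -0.16 for branched-chain and ketone genes (0.0168) and -0.20 for oxidative phosphorylation (6.66e-06). The other calls ended, at -0.16 for the tricarboxylic acid cycle (0.125), -0.01 for contractile genes (0.577) and 0.08 for ion channels (0.277). Without ACRE 4 alone the medians of the fatty acid, tricarboxylic acid cycle, branched-chain, contractile and ion channel lists were -0.49, -0.59, -0.59, -0.25 and -0.21, and without ACRE 2 alone those of the contractile and ion channel lists were -0.36 and -0.22. The ion channel call ended without ACRE 2, ACRE 4 or CMS7KO 2 (camera adjusted p = 0.415, 0.189 and 0.0778), and without CMS7KO 2 so did that of oxidative phosphorylation (-0.12, camera adjusted p = 0.112), whose median was -0.39 without CMS7KO 1. Scaling by library totals alone gave medians of -0.10 for oxidative phosphorylation, -0.35 for contractile genes and -0.30 for ion channels. This scaling moves the median of all genes to 0.14. Relative to other genes the contractile and ion channel lists were not weaker under it (camera adjusted p = 3.38e-06 and 0.0104, against 0.000216 and 0.0337 with TMM). With limma voom the fatty acid, tricarboxylic acid cycle, branched-chain, contractile and oxidative phosphorylation medians were -0.52, -0.57, -0.60, -0.26 and -0.16, and the ion channel call ended (-0.18, camera adjusted p = 0.133), as it did with a filter at 1 CPM (-0.51, 0.0536).

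The cell cycle, immediate-early, heat-shock and autophagy lists were also called lower under the preset correlation only, while the unfolded protein response, antioxidant and apoptosis lists were not called. Of 31 cell cycle genes 28 were lower and 3 higher in the libraries labelled CMS7KO (median log2 fold change -0.62, camera adjusted p = 4.80e-06, 0.637 with an estimated correlation), with 0 past the threshold adjusted over the list alone in edgeR, where 13 had an unadjusted p under 0.05. Top2a was at 24.2 ± 6.64 against 50.6 ± 24.9 CPM (SD, n = 4 each), Ccna2 at 11.8 ± 2.75 against 23.1 ± 9.42, Cenpf at 12.3 ± 2.54 against 23.0 ± 4.74 and Rrm2 at 10.4 ± 0.994 against 17.7 ± 5.69. The cell cycle scores overlapped between groups (exact permutation p = 0.229, 0.444 adjusted). ACRE 4 had the lowest score, -0.48, against 0.11 to 0.86 in ACRE 1 to 3 and -0.43 to 0.10 in CMS7KO. The median was -0.93 without ACRE 2 and 4 (camera adjusted p = 6.99e-24) and -0.35 without ACRE 3 (0.0205). Leaving out ACRE 4 thus removed the control that went the other way. These p rest on the preset correlation of 0.01, where the estimate for this list was 0.726. Of 23 immediate-early genes 16 were lower and 7 higher (median -0.16, camera adjusted p = 0.00506, 0.637 with an estimated correlation). Adjusted over the list alone 7 were lower, Fos, Fosb, Zfp36 and Dusp1 among them, and 2 higher. The median was 0.02 when scaled by library totals alone, which moves the median of all genes to 0.14, and the call ended without ACRE 2 and 4 (-0.10, camera adjusted p = 0.0859). The immediate-early median was -0.26 without ACRE 3, -0.08 without ACRE 4 and -0.25 without either CMS7KO 2 or CMS7KO 4. Of 17 heat-shock protein genes 16 were lower and 1 higher (median -0.36, camera adjusted p = 0.0177, 0.637 with an estimated correlation). Hspd1 was at 151 ± 44.7 against 299 ± 147 CPM, Hspb7 at 839 ± 234 against 1642 ± 963, Hspe1 at 57.8 ± 10.9 against 76.1 ± 10.6 and Hspa4 at 106 ± 14.5 against 168 ± 85.4. Of 20 genes of autophagy and muscle protein degradation 16 were lower and 4 higher (median -0.14, camera adjusted p = 0.0289, 0.726 with an estimated correlation). The ubiquitin ligase gene Trim63 was at 69.3 ± 15.2 against 131 ± 60.3 CPM and Fbxo32 at 51.1 ± 7.64 against 94.9 ± 48.7, Foxo3 at 45.8 ± 4.07 against 94.2 ± 49.5, and Atg5 at 13.04 ± 1.29 against 18.6 ± 5.97. Their median was 0.04 when scaled by library totals, where that call ended. The heat-shock and autophagy medians were 0.04 and 0.08 without ACRE 2 and 4, with both calls ended (camera adjusted p = 0.792 and 0.376). Both calls also ended with limma voom (-0.16 and -0.07). An offset for GC content and gene length gave -0.36 for the immediate-early and -0.24 for the autophagy list, and library totals gave -0.17 for the heat-shock list. The heat-shock call also ended without ACRE 2 or CMS7KO 2 (-0.11 and -0.22), and its median was -0.22 without ACRE 4. The autophagy call ended without ACRE 2, ACRE 4, CMS7KO 2 or CMS7KO 4 (-0.06, -0.03, -0.15 and -0.12), and its median was -0.23 without either ACRE 1 or ACRE 3.

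A ribosomal and 3 immune lists were called higher under the preset correlation only, and all 4 calls ended without ACRE 2 and 4. Of 39 cytosolic ribosomal protein genes 38 were higher and 1 lower in the libraries labelled CMS7KO (median log2 fold change 0.30, camera adjusted p = 4.18e-07, 0.637 with an estimated correlation). Rps19 was at 161 ± 12.3 against 108 ± 28.3 CPM (SD, n = 4 each), Rps16 at 189 ± 24.9 against 132 ± 35.1 and Rpl27 at 182 ± 11.6 against 136 ± 19.2. The ribosomal scores were lowest in ACRE 2 (-0.36) and ACRE 4 (-0.39), and without these libraries the median was 0.11 (camera adjusted p = 0.0705). All 16 antigen presentation genes were higher (median 0.48, camera adjusted p = 0.00151, 0.637 with an estimated correlation). H2-DMb1 was at 7.22 ± 2.75 against 3.77 ± 1.29 CPM, Ciita at 6.26 ± 3.50 against 3.47 ± 0.332, Psmb9 at 22.2 ± 11.2 against 13.4 ± 6.47 and Tap2 at 43.4 ± 14.6 against 33.2 ± 7.80. Their score was 1.24 in CMS7KO 4 and -0.15 to -0.04 in CMS7KO 1 to 3, and without CMS7KO 4 the median was 0.07 (camera adjusted p = 0.219). Of 36 interferon-stimulated genes 28 were higher and 8 lower (median 0.23, camera adjusted p = 0.0172, 0.752 with an estimated correlation). Ifi27l2a was at 47.6 ± 7.90 against 28.7 ± 11.9 CPM, Ifi47 at 9.95 ± 3.99 against 6.23 ± 2.12, Mx1 at 6.50 ± 2.96 against 3.75 ± 1.56 and Oas1a at 10.1 ± 3.12 against 7.35 ± 1.19. Of 28 cytokine and chemokine genes 20 were higher and 8 lower (median 0.39, camera adjusted p = 0.0432, 0.685 with an estimated correlation). Ccl8 was at 9.31 ± 5.27 against 3.61 ± 1.33 CPM, Cxcl16 at 30.4 ± 4.12 against 17.6 ± 6.88, Ccl21a at 25.5 ± 11.02 against 12.9 ± 4.80 and Cxcl1 at 2.77 ± 1.38 against 6.14 ± 4.29. The interferon call ended without ACRE 2 (median 0.04), ACRE 4 (0.17), CMS7KO 2 (0.17) or CMS7KO 4 (0.09). The cytokine call ended without ACRE 2, 3 or 4 (0.24, 0.36 and 0.23) or without CMS7KO 1, 2 or 4 (0.32, 0.31 and -0.02). With limma voom the antigen presentation median was 0.32, and the interferon and cytokine calls ended (0.14 and 0.17). The cytokine call also ended with library totals (0.53), no low-count filter (0.30), a stricter filter (0.32) and without the mitochondrial and 10 most abundant genes (0.34, camera adjusted p = 0.0567). Without ACRE 1 the antigen presentation and interferon medians were 0.89 and 0.49, and without ACRE 4 the former was 0.31. Without ACRE 2 the ribosomal median was 0.20. Without ACRE 2 and 4 the antigen presentation, interferon and cytokine medians were 0.11, -0.06 and 0.15, with all 3 calls ended. No member of these 4 lists passed the threshold in edgeR over all genes or adjusted over the list alone, where 10 members had an unadjusted p under 0.05 and a higher level.

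A further 4 cell type lists were called higher under the preset correlation only. Of 9 erythroid and platelet markers all were higher in the libraries labelled CMS7KO (median log2 fold change 0.75, camera adjusted p = 0.000565, 0.305 with an estimated correlation). Hbb-bs was at 522 ± 160 against 277 ± 88.3 CPM (SD, n = 4 each), Hba-a1 at 376 ± 75.7 against 224 ± 82.7, Hbb-bt at 36.1 ± 11.4 against 19.3 ± 7.55, and Hba-a2 at 30.4 ± 7.29 against 16.7 ± 8.92. All 10 B and plasma cell markers were higher (median 0.60, camera adjusted p = 0.0323, 0.305 with an estimated correlation). Ighm was at 24.0 ± 3.26 against 14.5 ± 4.51 CPM, Cd79a at 2.21 ± 0.818 against 0.785 ± 0.451, Jchain at 4.93 ± 8.08 against 0.514 ± 0.160 and Igkc at 36.0 ± 64.0 against 2.97 ± 1.51. Of 10 mesothelial and epicardial markers 7 were higher and 3 lower (median 0.19, mean 0.76, camera adjusted p = 0.0354, 0.305 with an estimated correlation). The keratins Krt18 and Krt8 (2.42 ± 0.910 against 0.433 ± 0.520 CPM) were higher adjusted over the list alone, Lrrn4 was at 0.757 ± 0.628 against 0.260 ± 0.364 CPM and Tbx18 at 8.81 ± 2.22 against 7.44 ± 2.66. Of 9 atrial cardiomyocyte markers 7 were higher and 2 lower (median 0.61, camera adjusted p = 0.0393, 0.305 with an estimated correlation). Adjusted over the list alone the natriuretic peptide gene Nppa (1046 ± 423 against 407 ± 225 CPM), Dkk3 (25.5 ± 7.75 against 12.9 ± 2.28) and Myl7 (0.887 ± 0.582 against 0.157 ± 0.109) were higher and Tbx5 (8.04 ± 1.88 against 19.2 ± 9.53) lower. The atrial genes Myl7 and Sln had at most 22 reads and at most 1 read in any library, and Myl4 had 25 to 92. Little RNA of atrial muscle was therefore read, although the hearts are described as whole. The call of this list does not measure atrial tissue. Without ACRE 2 and 4 the erythroid, B cell and atrial medians were 0.34, 0.33 and 0.68, with the calls ended (camera adjusted p = 0.0574, 0.253 and 0.0574), and the mesothelial median was 2.25 (0.00052). Scaling by library totals ended the B cell, mesothelial and atrial calls (0.70, 0.39 and 0.75), and limma voom the B cell and atrial calls (0.55 and 0.64). The mesothelial median was 1.32 with voom and 0.04 with the GC content and gene length offset. The B cell call ended without ACRE 2 (0.48) or CMS7KO 3 (0.35), and its median was 0.39 without ACRE 4. The atrial call ended without ACRE 1 (0.64), ACRE 3 (0.38) or CMS7KO 4 (0.31). It also ended with no low-count filter (0.56), a filter at 1 CPM (0.49), no sex covariate (0.49) and the GC offset (0.55). Without ACRE 3 and CMS7KO 3, left out after seeing the data, the atrial, B cell and mesothelial calls ended (0.45, 0.57 and 0.26; camera adjusted p = 0.0619, 0.0507 and 0.0507). The mesothelial call ended without ACRE 1, ACRE 3, CMS7KO 1 or CMS7KO 2 (0.13, 0.08, 0.20 and 0.06), and its median was 1.28 without ACRE 4, 0.46 without CMS7KO 3 and 0.47 without CMS7KO 4.

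Cardiomyocyte and vascular markers were not called. Of 12 cardiomyocyte markers 11 were lower and 1 higher in the libraries labelled CMS7KO (median log2 fold change -0.26, camera adjusted p = 0.0952), with Myh6 at 13931 ± 3183 against 27490 ± 13430 CPM (SD, n = 4 each), Hspb7 as above, Actc1 at 6639 ± 2135 against 10847 ± 4639 and Ryr2 at 695 ± 147 against 1151 ± 737. The list passed as lower without ACRE 3 or CMS7KO 1 (-0.38 and -0.34, camera adjusted p = 0.0335 and 0.046), with DESeq2 (-0.27) and with the GC content and gene length offset (-0.44). Its median was -0.15 without CMS7KO 2, -0.09 with library totals and -0.08 without ACRE 2 and 4 (camera adjusted p = 0.460, 0.0704 and 0.948). Of 12 endothelial markers 10 were higher and 2 lower (median 0.11, 0.0952), with Vwf at 123 ± 14.004 against 86.5 ± 22.5 CPM and Aqp1 at 555 ± 85.6 against 643 ± 376. The endothelial list passed as higher without ACRE 1 or ACRE 3 (0.37 and 0.35) and as lower without ACRE 2 and 4 (-0.30, camera adjusted p = 0.0114). Its median was -0.10 without ACRE 2, -0.04 without ACRE 4 and 0.02 without CMS7KO 2. Medians and camera adjusted p were 0.24 and 0.0952 for lymphatic endothelial, 0.65 and 0.0767 for T and natural killer cell, 1.84 and 0.0767 for adipocyte, 0.27 and 0.0967 for chondrocyte and bone and 0.51 and 0.112 for skeletal muscle markers. They were 0.04 and 0.655 for pericyte and smooth muscle, 0.05 and 0.66 for Schwann and neuronal and -0.00 (0.17 with library totals) and 0.359 for dendritic and mast cell markers. Leaving out CMS7KO 3 gave a call for the lymphatic list (0.53), whose median was 0.08 without CMS7KO 2. The chondrocyte and bone median was 0.65 without ACRE 3, 0.51 without CMS7KO 1 and 0.14 without ACRE 4. Leaving out ACRE 1 or CMS7KO 1, 2 or 3 gave a call for the T cell list (0.96, 0.93, 0.87 and 0.90), ACRE 4 or CMS7KO 2 or 3 for the adipocyte list (3.56, 1.92 and 2.59) and ACRE 2 for the skeletal muscle list (0.74). The adipocyte list also passed with DESeq2 (2.03, camera adjusted p = 0.00608) and without ACRE 2 and 4 (4.01, 0.0438). Its median fell to 0.59 without CMS7KO 4 and to 1.21 without ACRE 3 (camera adjusted p = 0.336 and 0.303). Without ACRE 3 and CMS7KO 3 the adipocyte, lymphatic and endothelial lists passed as higher (1.82, 0.50 and 0.27; camera adjusted p = 0.00351, 0.0275 and 0.0190). Named members of these lists were Pdpn (10.8 ± 1.91 against 7.13 ± 0.881 CPM), Cd3e (0.834 ± 0.849 against 0.132 ± 0.0741), Plin1 (2.24 ± 3.99 against 0.272 ± 0.463), Comp (42.2 ± 28.6 against 8.04 ± 7.18), Pvalb (1.05 ± 0.428 against 0.219 ± 0.0756), Abcc9 (207 ± 21.6 against 339 ± 148), Cdh19 (8.77 ± 1.83 against 10.8 ± 2.64) and Cpa3 (0.210 ± 0.142 against 0.824 ± 0.209).

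Load-induced and fetal cardiac genes showed no common direction. Of 20 such genes 10 were higher and 10 lower in the libraries labelled CMS7KO (median log2 fold change 0.05, camera adjusted p = 0.359). Adjusted over the list alone Nppa and Uchl1 (38.1 ± 3.60 against 17.2 ± 7.60 CPM; SD, n = 4 each) were higher and Enah (85.5 ± 5.52 against 154 ± 49.7) lower. The list passed without ACRE 2 (0.18, camera adjusted p = 0.0465) and without ACRE 2 and 4 (0.35, 0.000137). Medians and camera adjusted p of the other pathway lists not called were 0.29 and 0.0584 for BMP/Smad1/5 targets, 0.05 and 0.448 for TGF-beta superfamily ligands, receptors and Smads, 0.06 and 0.463 for basement membrane, 0.19 and 0.358 for integrins and -0.23 and 0.122 for ErbB and hypertrophic kinase signalling. They were -0.12 (0.04 with library totals) and 0.112 for the unfolded protein response, -0.24 and 0.358 for antioxidant genes, -0.02 (0.14 with library totals) and 0.636 for apoptosis and p53 targets, -0.14 (0.02) and 0.636 for clock genes, -0.15 (0.04) and 0.489 for glycolysis, 0.00 (-0.01 with DESeq2) and 0.742 for angiogenesis, -0.19 (0.02 with library totals) and 0.249 for mitochondrially encoded and -0.18 and 0.249 for sex-linked genes. The BMP/Smad1/5 list passed without ACRE 1 or CMS7KO 3 (0.51 and 0.28), the ErbB list without ACRE 1 or ACRE 3 (-0.35 and -0.29), and the unfolded protein response list without CMS7KO 4 (-0.19). With no low-count filter the ErbB and unfolded protein response lists passed (-0.20 and -0.13, camera adjusted p = 0.0296 and 0.0201). Without ACRE 3 and CMS7KO 3 the BMP/Smad1/5 and ErbB lists passed (0.42 and -0.31, 0.0405 and 0.0389). Median, mean and test differed in sign for the angiogenesis, apoptosis and pericyte lists. In fry 0 pathway and 0 cell type lists passed the directional test (smallest adjusted p 0.289 and 0.0872). The mixed test passed for 4 pathway lists (immediate-early, TGF-beta/Smad2/3 targets, matrix proteases and complement) and 5 cell type lists (skeletal muscle, atrial cardiomyocyte, macrophage, mesothelial and activated fibroblast).

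The sex labels were compared with sex-linked transcripts before the sex effect was read. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 225, 221, 224 and 0 reads per library total scaled as CPM in ACRE 1 to 4 and 216, 260, 238 and 0 in CMS7KO 1 to 4. Xist, the RNA of the inactive X chromosome, had 0.378, 0, 0.332 and 290 CPM in ACRE 1 to 4 and 0.686, 0.350, 0.607 and 828 in CMS7KO 1 to 4, where a count of 0 allows up to 0.174 CPM in ACRE 2. ACRE 3 and CMS7KO 3, labelled female, thus held 3377 and 3528 reads of Y-linked genes and 5 and 9 reads of Xist. In ACRE 4 and CMS7KO 4 the 0 reads of Y-linked genes allow up to 0.232 and 0.222 CPM. The sex label thus did not match the sex-linked transcripts in 2 of 8 libraries. It was the covariate of the genotype fits and list tests above, which therefore do not adjust for the sex these transcripts show.

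**Figure D4:**
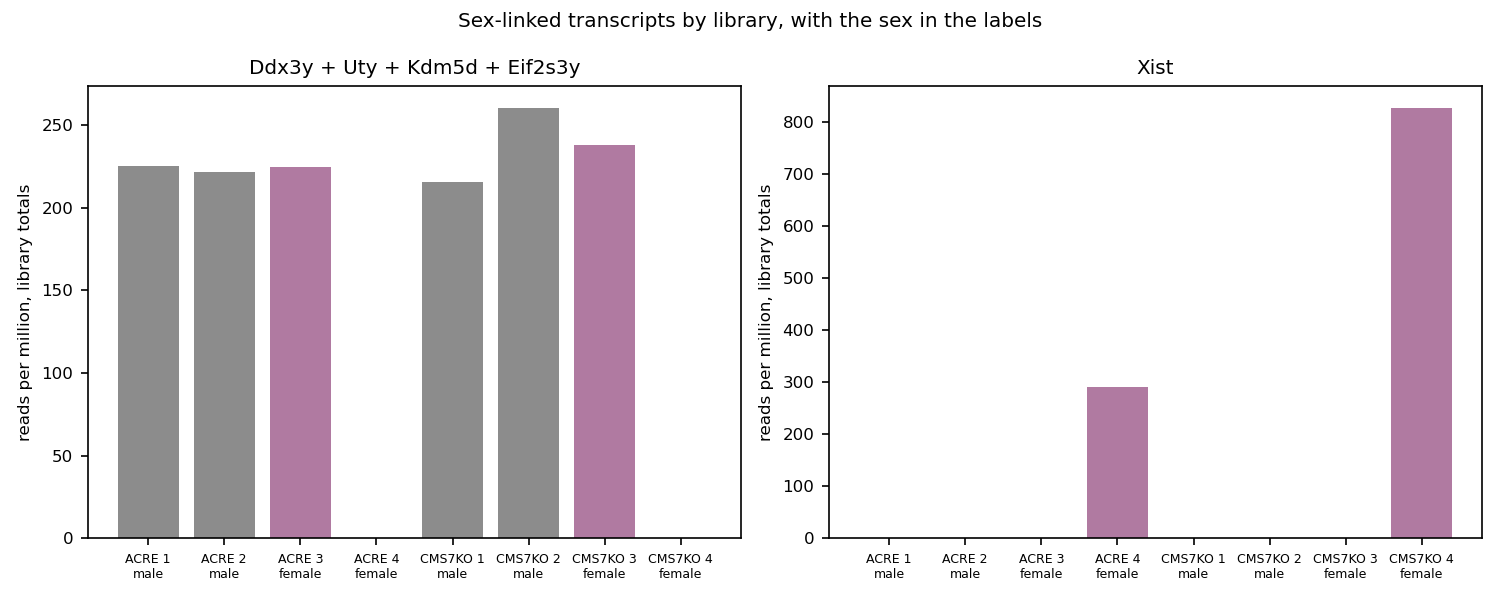
Summed level of 4 Y-linked genes (left) and level of Xist (right), scaled by library totals (y axes), in each library (x axis), grey where the label says male and purple where it says female. ACRE 3 and CMS7KO 3 are labelled female, with 224 and 238 for the Y-linked genes and 0.332 and 0.607 for Xist.

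Between the sex labels, 0 genes differed in edgeR (207 at an unadjusted p under 0.05, where chance gives 839), 0 in DESeq2 and 0 in limma voom. The smallest p outside X and Y, male minus female, belonged to Fbn2 (log2 difference 1.04), Smim38 (2.31), Nppa (1.03), Hoxd4 (3.07) and Zbed6 (1.12) on the male side. On the female side it belonged to Cidec (-4.37), a lipid droplet protein gene of adipocytes, Itih4 (-0.92), Bend6 (-0.97), Zfp36 (-0.68) and Ifi202b (-5.37). None passed adjustment (smallest adjusted p 1.00). Without ACRE 3 and CMS7KO 3, left out after seeing the data, 13 genes differed. They were chosen after their values were seen: Xist (-10.82), the Y-linked Ddx3y (13.41), Eif2s3y (13.20), Uty (11.68) and Kdm5d (11.57), the adipocyte genes Cfd (-4.58), Cidec (-5.38) and Plin1 (-5.07), the immunoglobulin genes Ighg1 (-7.44) and Ighg2c (-5.56), and Car3 (-4.80), Cyp2e1 (-4.05) and H2af-ps2 (-7.19). The female side then held ACRE 4 and CMS7KO 4 alone, with Plin1 at 0.965 and 8.22 CPM. For genes outside X and Y a sex difference therefore cannot be told apart from differences of these libraries.

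Whether the genotype effect differs between the sex labels was tested as an interaction. In edgeR 0 genes passed (178 unadjusted, where chance gives 839) and in limma voom 0, while DESeq2 called 2, the predicted genes Gm10800 (5.07) and Gm9824 (-3.44), chosen after their values were seen. The smallest p for a more positive effect under the male label belonged to B3galt1 (log2 difference 3.89), Pttg1 (2.03), the imprinted H19 (2.58), Elovl7 (6.53) and Zfp619 (1.89), and for a more negative effect to Plekha7 (-2.61), Trac (-5.44), Tbc1d10c (-2.50), Blk (-1.60) and Ush1c (-0.95). None of these 10 passed (smallest adjusted p 1.00 in edgeR), and without ACRE 3 the count was 1. Within the libraries labelled male 0 genes differed by genotype (edgeR, 805 unadjusted), and within those labelled female 0 (972). Because 2 sex labels did not match sex-linked transcripts, these counts describe the labels and not the sex of the hearts.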

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

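Tests chosen only after the result was seen were those of the sex labels, of the share of cardiomyocyte RNA, of the GC content and gene length trend, of the chromosomes of the called genes, and of pseudogene reads, while the counts over other splits and the tests of linked alleles and haplotypes were planned.

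In 188 groups of 4 libraries, 19 values lay far from the other 3 of their group by Dixon's gap test. About 9.4 would be given by unselected, normally distributed values. The CPM were not log-transformed and the genes were picked by their p in these libraries, so 19 against 9.4 does not measure an excess. Among genes named for the genotype, Fosb reached 9.65 CPM in ACRE 4 (others 4.36 to 5.02), Wnk2 106 CPM in ACRE 4 (others 50.3 to 59.3) and Fzd2 9.25 CPM in ACRE 2 (others 5.56 to 6.15), while Gm31663 was at 0 CPM in CMS7KO 2 (others 0.190 to 0.224). Among genes named for the sex label, Cidec reached 3.09 CPM in ACRE 4 (others 0 to 0.440) and 12.6 CPM in CMS7KO 4 (others 0.363 to 0.580), and Ifi202b 3.77 CPM in ACRE 4 (others 0 to 0.188) and 4.74 CPM in CMS7KO 3 (others 0 to 0.145). Hoxd4 and Zbed6 reached 0.644 and 20.8 CPM in ACRE 1 (others 0.0628 to 0.0965 and 4.44 to 7.03). Among genes named for the interaction, Elovl7 reached 9.27 CPM in ACRE 4 (others 0.377 to 0.469) and Blk was lowest in CMS7KO 2 at 21.8 CPM (others 34.7 to 35.6).

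The list scores that stood apart fell mainly on CMS7KO 4. Its adipocyte score was 2.82 (others -0.36 to -0.14), its antigen presentation score 1.24 (others -0.15 to -0.04) and its angiogenesis score -0.14 (others 0.05 to 0.08). The sex-linked scores were -1.60 in ACRE 4 (others 0.51 to 0.70) and -1.83 in CMS7KO 4 (others 0.53 to 0.58). The TGF-beta/Smad2/3 target score was 0.49 in CMS7KO 2 (others 0.06 to 0.12). The mitochondrial share of reads was 16.4% in ACRE 1 (others 20.9 to 21.2%).

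ACRE 3 and CMS7KO 3 are labelled female and carried Y-linked reads with almost no Xist. Male RNA mixed into female libraries would leave Xist near its female level, and Xist in these libraries reached 0.209% of the lowest level in the other libraries labelled female, which argues against it. An exchanged sex label or heart may explain the values, since their Y-linked level was 1.00 times that of the libraries labelled male. The libraries labelled male all held Y-linked reads, at 216 to 260 CPM, and at most 0.686 CPM of Xist. This argues against an exchange of these hearts with a library labelled male in this series. Which of the label and the heart was exchanged stays open, and so does the genotype label of ACRE 3 and CMS7KO 3. No biological explanation was tested.

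Oxidative, contractile and conduction lists were lower and matrix lists higher in the libraries labelled CMS7KO, where Smad7 was not lower, and a smooth trend on GC content and gene length is argued against as the whole cause, since 19 of 19 pathway calls remained after its removal. A smaller share of cardiomyocyte RNA, tested by the gap between the activated fibroblast and endothelial scores (0.82 between groups, exact permutation p = 0.114), cannot be told apart from a change within cells for the matrix, contractile, conduction and oxidative phosphorylation lists with 4 libraries per group. Without ACRE 2 and 4 the matrix medians changed little, and those of fibroblast and macrophage markers were 0.56 and 0.58. The cardiomyocyte, endothelial and pericyte medians were -0.08, -0.30 and -0.17 there. A smaller share alone would also raise endothelial and pericyte markers, but it is not settled by these values, since their library scores overlapped between groups. It stays open for the fatty acid, tricarboxylic acid cycle and branched-chain lists too: their mean score differed by -0.44 more than the cardiomyocyte score (exact permutation p = 0.0286, the smallest possible; 0.0857 to 0.114 per list, adjusted over 6 lists), but this rests on ACRE 2 and 4 (0.40 and 0.54 above it, against -0.29 to 0.02 in the other 6 libraries). The median of the cardiomyocyte markers, -0.26 (SD 0.383), lay 0.59 to 0.70 above the medians of these 3 lists, 0.28 to 0.38 above them without ACRE 4 (SD 0.254) and only 0.07 to 0.11 above them without ACRE 2 and 4, left out after seeing the data (SD 0.299). A difference by genotype stays open, and chance is not excluded for the list counts: 6 of 35 splits of the 8 libraries gave at least as many pathway lists (19, highest other 20) and 6 of 35 as many cell type lists (7, highest other 10).

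The 6 genes called by genotype may instead reflect alleles that differ between the groups, but 5 of the 6 lie on other chromosomes than Smad7, which argues against their own alleles being linked to it. Within 20 Mb of Smad7, 3 of 167 genes (1.80%) had an unadjusted p under 0.01 against 3.79% elsewhere (odds ratio 0.464, Fisher exact p = 0.221), so no excess was seen there. An odds ratio under 1 had been set beforehand as counting against linked alleles, but Fbn2 is the only called gene among these and was not tested alone, so it stays open, as do untested alleles at other loci and effects of linked alleles on distant genes. Among 18 genes outside X, Y and the mitochondrial genome that were read in some libraries and nearly absent from others, only 2 had such a neighbour within 5 Mb and these 2 shared their pattern (shuffles 0.104 on average), too few to decide on haplotypes. Of the 18, 10 were pseudogenes, 55.6% against 4.20% of other tested genes (odds ratio 28.5, Fisher exact p = 5.85e-10). Reads shared with a parent gene would give such an excess. No parent gene or read mapping was examined, so the excess does not tell shared reads from haplotypes. While 0 of the 18 followed the genotype, only 0.840% of the possible patterns do, so this count decides nothing. The called pseudogene Gm31663, at 0 to 0.224 CPM in CMS7KO and 2.28 to 8.01 CPM in ACRE, fell outside the 18.

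Other splits of the 8 libraries into 4 and 4 show how far chance reaches for the gene counts. The 6 genes by genotype were matched by 1 of 35 splits, the real one (highest other 0), and so were the 8 genes without the sex covariate (1 of 35, highest other 0). This does not exclude chance, since 1 of 35 is the lowest share that the splits can give. The other splits mix the genotypes, so any genotype difference widens their spread and lowers their counts. All 6 calls are lost without CMS7KO 1, 2 or 3, and at an unadjusted p under 0.05 3 other splits had more genes (3944, 3218 and 2591) than the 2571 by genotype. With DESeq2, 3 of 35 splits called at least the 403 genes of the genotype split. ACRE 1, 2 and 4 with CMS7KO 1 against the others gave 1710, which points to a structure of the samples, and chance is not excluded for the DESeq2 count. For the sex label 0 genes were called (edgeR, 207 unadjusted, 0 in DESeq2 and 0 in voom), which all 35 splits reach by definition, so this count decides nothing on chance. There ACRE 1, ACRE 3, CMS7KO 2 and CMS7KO 3 against the others gave 1609, again a structure of the samples.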

How the results depend on the processing

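The alternatives without ACRE 2 and 4, without ACRE 3 and CMS7KO 3, with the GC content and gene length offset and with the bias-adjusted quasi-likelihood were tests chosen after the data were seen, and the others were fixed beforehand and all run.

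The 3 genes higher in CMS7KO became 214 with DESeq2, 456 with no low-count filter, 1 with the replicate block, 86 without ACRE 2 and 4 and 0 without ACRE 3 and CMS7KO 3 (edgeR, 2498 unadjusted). The 3 genes lower in CMS7KO became 189 with DESeq2, 5 with limma voom, 912 with no filter, 5 with no sex covariate, 89 without ACRE 2 and 4 and 1 without ACRE 3 and CMS7KO 3. Leaving out 1 library gave 0 (CMS7KO 1, 2 or 3) to 10 higher (ACRE 2) and 0 to 7 lower. With no filter edgeR's prior degrees of freedom had no finite value, against 3.86 to 4.50 with it. Elsewhere the cause was not tested. The block rests on replicate numbers that do not pair the libraries: deviations of libraries with the same number correlated at -0.17, -0.19, 0.12 and 0.20, and only ACRE 4 correlated best with its own number. Of the 6 called genes the block kept 3, losing Nrtn, Grhl1 and Gm31663. DESeq2 kept all 6, voom lost Grhl1, no sex covariate lost Fbn2, the GC offset lost Nrtn and Gm31663, and only ENSMUSG00000120208 was kept without ACRE 3 and CMS7KO 3.

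The 0 genes by sex label (edgeR, 207 unadjusted; DESeq2 0, voom 0) became 70 with no filter and 13 without ACRE 3 and CMS7KO 3. The 0 interaction genes (edgeR, 178 unadjusted; voom 0) became 2 with DESeq2, 8 with no filter and 1 without ACRE 2 and 4, and leaving out 1 library gave 0 to 1 (ACRE 3).

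With an estimated correlation 0 pathway and 0 cell type lists were called higher or lower (camera). Without ACRE 2 and 4 the 9 pathway lists higher became 5, 4 of them shared, the 10 lower became 4, all shared, and the 0 cell type lists lower became 1. The 7 cell type lists higher became 4 with library totals, and 1 was lower with DESeq2 and with the GC offset. Leaving out 1 library gave 6 to 10 pathway lists higher, 6 (CMS7KO 2) to 11 lower, 6 to 10 cell type lists higher and 0 to 1 lower (ACRE 3 or CMS7KO 1). These counts include the neutrophil list, which had too few tested genes with all 8 libraries and was called higher without ACRE 2, ACRE 4, CMS7KO 2 or CMS7KO 3 (medians 1.37, 1.11, 1.17 and 1.39), and without ACRE 2 and 4 (2.39).

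Smad7 kept its direction and was not called under any alternative, from 0.09 (GC offset) to 0.45 (library totals), and from 0.16 (without ACRE 4) to 0.43 (without CMS7KO 1) with 1 library left out. For the other genes named by genotype no alternative reversed the direction. With Smad7 included, values kept their side of the threshold 261 times, passed it 49 times and lost it 12 times, and with 1 library left out 155, 3 and 26 times. The 261 include the log2 CPM means, which have no test and were counted by direction alone.

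Without ACRE 2 and 4 the tested direction reversed for these lists, given with their medians: endothelial -0.30, pericyte -0.17, Schwann -0.36, angiogenesis -0.11, antioxidant 0.025, apoptosis 0.067, autophagy 0.085, basement membrane -0.091, ion channels 0.083, ErbB 0.064, glycolysis 0.16, interferon -0.065 and mitochondrially encoded 0.15. The heat-shock median changed sign there too (0.041), with its tested direction kept and its call ended. Without ACRE 3 and CMS7KO 3 the tested direction reversed for load-induced genes at -0.083. The GC offset reversed that of the pericyte list at -0.028, DESeq2 the angiogenesis list at -0.0080 and no filter the same list at -0.0015. With voom the tested direction reversed for glycolysis (0.018), apoptosis (-0.043) and clock genes (-0.062), the last 2 with medians of unchanged sign.

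Other medians changed sign while the tested direction was kept. With the GC offset these were Schwann -0.15, basement membrane -0.080, angiogenesis -0.040, load-induced -0.0041, apoptosis 0.029 and dendritic 0.073. With library totals, which move the median of all genes to 0.14, they were dendritic 0.17, apoptosis 0.14, glycolysis 0.044, autophagy 0.037 (call ended), endoplasmic reticulum stress 0.037, mitochondrially encoded 0.021, immediate-early 0.018 and clock 0.017. The angiogenesis median also did so with DESeq2 size factors (-0.0070), voom (-0.0054), the replicate block (-0.0072) and without the mitochondrial and 10 most abundant genes (-0.0038). So did the dendritic median with the last 2 (0.032 and 0.050) and the bias-adjusted fit (0.061), basement membrane with voom (-0.019), load-induced with the 1 CPM filter (-0.038) and apoptosis with that filter (0.0017) and without ACRE 3 and CMS7KO 3 (0.012). The cytokine call ended with the replicate block (0.30, camera adjusted p = 0.0575), and the adipocyte and BMP/Smad1/5 lists passed with it (1.98 and 0.42, camera adjusted p = 0.00743 and 0.0484).

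With 1 library left out the tested direction reversed for 10 lists, none called with all 8 libraries. Their medians ranged from -0.51 to 0.36 for dendritic, -0.081 to 0.19 for pericyte, -0.22 to 0.47 for Schwann, -0.19 to 0.17 for angiogenesis, -0.066 to 0.022 for apoptosis, -0.079 to 0.18 for basement membrane, -0.20 to -0.039 for clock, -0.29 to 0.0053 for glycolysis, -0.048 to 0.19 for load-induced and -0.036 to 0.12 for TGF-beta superfamily genes. The cause was not tested, beyond there being fewer libraries and a low-count filter that then kept 17732 to 18043 genes against 16780. A library alone in its combination of genotype and sex label was assumed to vary like the others. Depth limits genes with few reads and not Smad7 with 248 reads or more.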

Other observations

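The genes named here were chosen after their values were seen, and no test was made of them. Heart muscle transcripts differed widely between the control libraries. Myh6, the main myosin of the adult mouse heart, stood at 32496 CPM in ACRE 2 and 44054 in ACRE 4, against 18828 in ACRE 1, 14582 in ACRE 3 and 9574 to 17079 in the libraries labelled CMS7KO. The calcium pump gene Atp2a2 stood at 10228 and 15555 CPM in ACRE 2 and 4, against 3299, 3045 and 1609 to 3325. The titin gene Ttn followed, at 5104 and 6183 CPM against 2811, 2644 and 2487 to 3300.4. The endothelial genes Pecam1 and Fabp4 went the other way, with 207 and 534 CPM in ACRE 2 and 278 and 530.4 in ACRE 4, against 429 and 1257 in ACRE 1, 473 and 1184 in ACRE 3, and 289 to 407 and 840.1 to 1144 in the libraries labelled CMS7KO. Of the matrix genes, Postn reached 1315 CPM and Col1a1 1140.5 in CMS7KO 2, against 372 to 695 and 476 to 736 in the other 3 libraries of its label.

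In CMS7KO 4 single genes of fat, plasma and antigen-presenting cells stood above the other libraries, while Ighm was highest in CMS7KO 3 (27.7 CPM, against 25.8 in CMS7KO 4). The immunoglobulin light chain gene Igkc stood at 132 CPM there and at 1.41 to 5.14 elsewhere, Cd74 at 389.9 against 71.7 to 164 and H2-Aa at 158 against 24.6 to 63.8. The fat cell genes Adipoq and Plin1 stood at 7.10 and 8.22 CPM against at most 1.45 and 0.965 elsewhere, with ACRE 4 next. Hbb-bs, of red blood cells, was at 726 CPM in CMS7KO 4 and 175 to 573 elsewhere.

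Some genes were read in some libraries and nearly absent from others without following the genotype. Trim12a was at 0 CPM in CMS7KO 2 and 4 and 5.70 to 27.4 elsewhere, and its neighbour Trim5 was at 0 and 0.0747 CPM in the same libraries. Slc15a2 was at 0.603 CPM in ACRE 2 and 0.882 in CMS7KO 2 and at 12.6 to 28.2 elsewhere. Rps3a2 was at 0.761 to 2.15 CPM in ACRE 1 to 3 and 41.3 to 124 in the other 5 libraries.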
